A study of Arabidopsis thaliana with 12 samples.

How the data were processed

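Total RNA came from the aerial parts of seedlings of Arabidopsis thaliana. Per the labels' protocols, plants grew for 9 days in continuous white light at 22 °C and were then treated for 24 hours with white light alone or with supplemental far-red light, without or with ABA. The labels print the intensities as 80 (white) and 6 (far-red) mmol per square metre and second and the ABA dose as 1 mM; whether the prefixes are those intended could not be checked, and the size of the dose is not used in any comparison. RNA was extracted with TRIreagent, treated with DNase and cleaned on RNeasy columns, then converted to biotin-labelled cRNA from an oligo-dT primer with a T7 promoter and hybridised to 1-colour Affymetrix arrays. Each of the 4 groups had 3 arrays, assigned by the sample titles.

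The values used are the log2 expression values per probe set that the authors deposited, which come from robust multi-array averaging (RMA) with the affy package per the submitters' processing notes. RMA subtracts background, sets the arrays to a common distribution and summarises the probes of a set, so that most uniform shifts between arrays are removed before any comparison and low values are compressed. The deposited values were not of identical distribution between arrays, which is why other scalings were tried. Detection calls (present, marginal, absent) were also deposited, from the MAS5 algorithm per the submitters' processing notes, and were used for filters and for bounds. Versions of these tools and the genome build are not given in the sources used here. The value table of the series and the matrix of all samples held the same values to within 5.0e-09.

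The file held 22810 probe sets. The 64 control probe sets were left out of the tests, and 22746 were tested. Names came from the platform's annotation table: 13513 probe sets were listed with 1 gene, 503 with several and 8730 were not listed, and the latter are unnamed here. Of those with 1 gene, 13436 were matched by gene identifier to the RefSeq gene table (assembly TAIR10.1), from which current symbols were taken, and 77 kept the name of the platform table. They stood for 13355 genes, 147 of which had more than 1 probe set. None of the named genes was among these, so the planned mean over the probe sets of a gene gave no other value. Because only part of the array is named, gene lists were measured in part, and RD29B, RAB18, HB-2, PIL1 and HFR1, fixed as checks of the treatments, were not analysed here. No coordinates are given because no build is named. Probe sets marked as shared between genes numbered 1061.

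Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with a mean per group on all 12 arrays, contrasts, eBayes and Benjamini-Hochberg adjustment over all probe sets, two-sided, with a threshold of 0.05 on the adjusted p. The fit had 8 residual degrees of freedom and a prior of 7.21. The contrasts were ABA in white light, ABA under far-red light, far-red without ABA, far-red with ABA and their interaction, and the averaged ABA and far-red effects, whose errors are independent of each other and of the interaction. Response sizes were compared by the median interaction over probe sets called on an averaged effect, with 400 permutations of the labels of the other factor within levels, and with the rotation test fry. In the fits with a block or array weights fry alone gave the p of the response sizes. A fold for a gene called absent on every array of a group is a lower bound, against the mean of, per array, the higher of the gene's own value and the lowest value of a probe set called present there, which lay between 2.46 and 2.80 log2 units. No fold is given against a group with no present call in which some calls were marginal. Other p-values of comparisons between groups come from exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

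The groups, the tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. Exceptions were the families of genes by symbol, the rotation test of response sizes and some tests of explanations, which are named as such where they are given. In each pairwise contrast the text names, among probe sets of a single gene past the threshold whose groups do not overlap, the 6 largest rises and the 6 largest falls, and for the 8 lists with the largest called share the called member with the largest rise and fall; up to 4 called members of a list may serve as examples, and members that were not called are given as values. For the interaction those that passed would be named.

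The 23 lists, from textbook knowledge, with measured of listed genes, were ABA-responsive genes (6 of 36), shade markers (5 of 23), early auxin response (6 of 26), phytochromes and PIFs (1 of 15), expansins and xyloglucan endotransglucosylases (8 of 22), gibberellin synthesis and signalling (3 of 18), light-harvesting complex proteins (3 of 20), Rubisco small subunits and Calvin cycle (3 of 11), flavonoid and anthocyanin pathway (4 of 22), circadian clock (1 of 17), jasmonate (2 of 15), salicylate (1 of 14), senescence (2 of 13), wax and lipid transfer (1 of 16), cell cycle (3 of 18), stomatal lineage (3 of 11), root markers (2 of 16) and reference genes (3 of 7). No member of the PYR/PYL receptors (11 listed), clade A PP2C phosphatases (9), ABA synthesis and breakdown (14), brassinosteroid synthesis (8) or raffinose synthesis (6) had a named probe set, and these lists were not analysed here. IAA29 is in both the shade and the auxin list. Lists with at least 3 measured members were tested with camera (preset correlation 0.01, adjusted over lists within a contrast), with a correlation estimated per list and fry as alternatives. camera compares the list with all other probe sets, while fry asks whether the genes of the list move, on balance, in 1 direction.

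The alternatives were the replicate number as a block, the series value table, quantile normalization of the deposited values, centring each array on its median, limits to the upper 60 percent of probe sets by mean (13647 kept) or to those called present on all arrays of a group (14401 kept), leaving out shared probe sets (21685 kept), an intensity-trended robust eBayes, array weights, fits of only the groups compared, a minimum of 2-fold, and leaving out each array in turn. Centring adds 1 amount to all values of an array, so it moves the differences of all probe sets in a comparison alike. In leave-one-out fits the groups share an estimate of spread. The procedure was tested on simulated data built from the real probe sets, with 200 changed probe sets in each of 5 simulations: for the ABA effect in white light, over 22746 probe sets, it recovered 57.6% of changes of 0.5 log2 units, 98.2% of 1 and 100% of 2, with 5.33% of the calls false, and for the interaction 27.2%, 84.5% and 99.4%, with 4.10% false. The simulated noise was independent between probe sets, so these shares need not hold where errors are shared across the probe sets of an array.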

Results

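Transcript levels were measured in the aerial parts of 10-day-old Arabidopsis thaliana seedlings that had spent their last 24 hours under 1 of 4 conditions. Plants received white light alone or white light with supplemental far-red light, which lowers the ratio of red to far-red light as a leaf canopy does. Each light condition was given without or with abscisic acid (ABA), a hormone of drought and seed maturation. The 4 groups, called white light, white light with ABA, far-red and far-red with ABA here, had 3 arrays each, 12 in all. The labels call the 3 arrays of a group biological replicates, and the p-values measure the spread between them. The series was designed to follow either factor in the background of the other. The comparisons are therefore the ABA effect in each light condition, the far-red effect at each ABA level, and the interaction. The number of arrays limits the precision, with a median standard error of 0.101 log2 units for a difference between groups and 0.144 for the interaction.

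The arrays of a group resembled each other closely. Pearson correlations between log2 values ranged from 0.995 to 0.998 over the 12 pairs within groups and from 0.988 to 0.997 over the 54 pairs between groups. The first principal component held 37.7% of the variance and separated the arrays by ABA. The next held 20.3% and separated them by light, with white light replicate 2 at a score of 7.83 on it and the other white-light arrays at 18.6 and 21.9. Array medians lay between 5.45 and 5.62 log2 units, and the share of probe sets called present between 60.6% and 67.2%. The far-red arrays had a median 0.09 log2 units higher than the white-light arrays (exact permutation p = 0.1, two-sided, the smallest that 3 arrays against 3 allow). Adding ABA in white light went with 3.20 more percentage points of present calls (exact permutation p = 0.1) and a median 0.055 log2 units higher (exact permutation p = 0.1). Between far-red with ABA and white light with ABA the share of present calls differed by -2.76 percentage points (exact permutation p = 0.1). Far-red replicate 3 had the highest median, the highest share of present calls and the smallest GAPDH 3′ to 5′ difference, 0.36 log2 units in a range of 0.36 to 0.99. The root expansin markers EXPA7 and EXPA18 lay between 3.52 and 4.08 log2 units in all 4 groups, and their differences did not pass the test in any comparison. Among commonly used reference genes, AT2G28390, AT4G34270 and PEX4 were measured. None of the 3 was called in any comparison by limma, with 0 called also when adjusted over the list alone. The sign of their median changed with the scaling for the ABA effect in white light, from 0.02 to -0.03.

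In white light, the largest rise with ABA under the naming rule, which leaves out unnamed probe sets, was that of AT2G37870. This gene encodes a protein of the lipid-transfer family. It rose 15.0-fold (log2 difference 3.90, SE 0.13, n = 3 against 3, limma adjusted p = 2.4e-11). AT4G33550, of the same broad family, rose 9.96-fold (3.32, SE 0.11, adjusted p = 2.0e-11). COR15A (AT2G42540), a cold-regulated chloroplast protein that protects membranes, rose from 7.61 ± 0.44 to 10.8 ± 0.21 log2 units (mean ± SD, n = 3), or 9.26-fold. AT3G02480, a late-embryogenesis-abundant protein, rose 8.60-fold with an SE of 0.32 log2 units. AT3G53980, a further member of the lipid-transfer family, and AT4G36700, a cupin-domain protein, rose 6.95-fold and 5.18-fold. The largest fall under the naming rule was that of AT4G11290, a peroxidase gene called absent on all 3 arrays with ABA, which was at least 4.80-fold lower there. AT5G28630 was likewise at least 3.47-fold lower, and AT5G20790 fell 3.99-fold (-2.00, SE 0.12). AT3G06070 fell by 1.87 on the log2 scale and AT4G21870 fell by 1.86 on the log2 scale. EXPA8 (AT2G40610), an expansin that loosens cell walls, fell 3.38-fold (SE 0.33, adjusted p = 0.0042).

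Of the 36 listed ABA-responsive genes 6 were measured and all of them rose in white light, also when adjusted over the list alone (6 of 6). Besides COR15A, the dehydrin LTI30 (AT3G50970) rose by 2.37 log2 units (SE 0.27), COR15B by 1.62 (SE 0.21) and COR47 by 0.61 (SE 0.14). LEA4-5, of the late-embryogenesis-abundant proteins, was called absent on all white-light arrays and rose at least 3.31-fold. The linker histone gene HIS1-3 was called absent on 2 of them. The median of the list was 1.79 log2 units (limma camera adjusted p = 5.8e-14, and adjusted p = 0.0224 with an estimated correlation, the highest over its alternatives, whose lowest was 8.0e-16). The 4 measured genes of the flavonoid and anthocyanin pathway also rose together, all 4 when adjusted over the list alone. DFR (AT5G42800), the dihydroflavonol reductase, rose by 1.51 (SE 0.14), the glycosyltransferase gene UF3GT (AT5G54060) by 1.62 (SE 0.17), AT4G14090 by 1.56 and AT5MAT (AT3G29590) by 1.3. Their median was 1.54 (adjusted p = 1.3e-10, and adjusted p = 0.0349 with an estimated correlation, in a range of 1.5e-11 to 0.0349 over the alternatives). SAG29 (AT5G13170), a sugar transporter gene of the senescence list, rose by 1.59 log2 units. WRKY53 of the same list had a difference of 0.48 (SE 0.19, adjusted p = 0.157). Adjusted over the list alone both passed.

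Few members of the growth-related lists were called in white light. EXPA8 alone of 8 expansins and xyloglucan endotransglucosylases fell (2 adjusted over the list alone; median -0.11, camera adjusted p = 0.104). Of 3 stomatal lineage genes, SPCH (AT5G53210), the transcription factor that starts the lineage, fell by 0.35 on the log2 scale. Its detection calls ran the other way, absent on 2 of 3 white-light arrays and present on all 3 with ABA. FMA and MUTE did not pass (1 adjusted over the list alone, camera adjusted p = 0.657). Of 6 early auxin response genes, WES1 (AT4G27260), an auxin-conjugating enzyme, rose by 0.68 (1 adjusted over the list alone). The list had a median of -0.04 but a mean of 0.07 and an upward test (adjusted p = 0.734). BIM1 rose by 0.39 among 5 shade markers (1 adjusted over the list alone; median -0.07, adjusted p = 0.734). HYH, a light-signalling transcription factor, fell by 0.36 as the only measured member of the phytochrome and PIF list (1 adjusted over the list alone). The 3 gibberellin receptors GID1A, GID1B and GID1C (1 adjusted over the list alone; median 0.09, adjusted p = 0.480), the cell cycle genes PRL, AUR1 and AUR2 (-0.11, adjusted p = 0.480), the Calvin cycle genes RCA, PRK and SBPASE (0.08, adjusted p = 0.617) and LHCB4.1, LHCB4.2 and LHCB4.3 of the light-harvesting complex (median 0.02, mean -0.01, downward test, adjusted p = 0.937) had no member past the threshold over all probe sets. The same held for the clock gene GI (-0.10), the jasmonate markers PDF1.2 (-1.22, SE 0.45, adjusted p = 0.139; 1 adjusted over the list alone) and THI2.1 (0.09), the salicylate marker GRX480 (0.01) and the wax synthase gene WSD1 (0.35, SE 0.11, adjusted p = 0.0703; 1 adjusted over the list alone).

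Over all 22746 probe sets, limma called 1463 different between white light with and without ABA, 914 higher and 549 lower (62.5% higher), of which 160 changed at least 2-fold. With each array centred on its median the split became 703 higher and 900 lower (43.9% higher). The median difference over all probe sets was then -0.057, against -0.0022 as deposited. Without white light with ABA replicate 1 the count was 908 and without its replicate 2 it was 949. COR47 lost its call without white light replicate 2 (0.41), white light with ABA replicate 1 (0.55) or 3 (0.59). BIM1 lost it without white light replicate 3 (0.30), white light with ABA replicate 1 (0.36) or 3 (0.37). SPCH lost it without white light replicate 1 (-0.32) or 2 (-0.30) or white light with ABA replicate 1 (-0.34) or 2 (-0.32), with an intensity-trended robust variance or with only the groups compared in the fit. HYH lost its call without white light replicate 1 (-0.38) or 2 (-0.28), white light with ABA replicate 1 (-0.37), 2 (-0.38) or 3 (-0.35), far-red replicate 1 or 2, or far-red with ABA replicate 3 (-0.36 in each of these last cases).

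Under supplemental far-red light AT2G37870 again had the largest ABA rise under the naming rule, 14.7-fold (3.88, SE 0.13, adjusted p = 3.3e-11). AT4G33550 rose 8.67-fold, the dehydrin gene LTI30 8.23-fold (SE 0.27, adjusted p = 5.2e-06), AT3G53980 7.95-fold and COR15A 7.59-fold. SAG29 rose 5.06-fold, from 6.11 ± 0.10 to 8.45 ± 0.21 log2 units (n = 3, adjusted p = 3.4e-07). AT4G11290 was again called absent on every array with ABA and was at least 3.55-fold lower. The glutaredoxin gene AT2G47880 was also lower with ABA, where it was called present on no array, so its fold is not given (adjusted p = 6.6e-05). BGLU28 (AT2G44460), a beta-glucosidase, fell 3.27-fold from a level that varied between far-red arrays with an SD of 0.96. EXPA8 fell 2.99-fold (SE 0.33, adjusted p = 0.0069), AT5G20790 2.91-fold and the lectin gene AT3G16530 2.83-fold.

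All 6 measured ABA-responsive genes rose under far-red light too, also when adjusted over the list alone (6 of 6), with a median of 1.66 log2 units (camera adjusted p = 6.2e-13, and adjusted p = 0.0283 with an estimated correlation, in a range of 9.3e-15 to 0.0283 over the alternatives). Examples besides LTI30 and COR15A were LEA4-5 (at least 3.3-fold), COR15B (1.39) and COR47 (0.79, SE 0.14). The 4 flavonoid pathway genes rose as well, all 4 adjusted over the list alone. Their values were DFR at 0.88 (SE 0.14), UF3GT at 0.92, AT4G14090 at 0.87 and AT5MAT at 0.53 (SE 0.15) and a median of 0.87 (camera adjusted p = 3.3e-05). For this list the call was lost with adjusted p = 0.208 with an estimated correlation, in a range of 1.1e-06 to 0.208 over the alternatives.

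Some members of other lists were called with ABA under far-red light, while the camera tests of these lists, where run, did not pass. The stomatal lineage genes SPCH and FMA fell by 0.47 and 0.29 on the log2 scale (SE 0.09 each). SPCH was called present on all 3 far-red arrays and absent on 2 of 3 in far-red with ABA. MUTE did not pass over all probe sets but did when adjusted over the list alone (3 of 3; median -0.29, camera adjusted p = 0.253). EXPA8 and XTH19, a wall-modifying hydrolase, fell among 8 expansins and xyloglucan endotransglucosylases (4 adjusted over the list alone; median -0.24, adjusted p = 0.188). WES1 rose by 0.71 and GH3.3, another auxin-conjugating enzyme, fell by 0.66 on the log2 scale among 6 early auxin genes (2 adjusted over the list alone; median -0.09, adjusted p = 0.771). YUC2, an auxin synthesis gene, fell by 0.53 on the log2 scale among 5 shade markers (3 adjusted over the list alone; median 0.12, mean -0.01, upward test, adjusted p = 0.771). AUR1, a mitotic kinase, fell by 0.32 on the log2 scale (2 of 3 cell cycle genes adjusted over the list alone; median -0.32, adjusted p = 0.107). GID1A rose by 0.41 (1 of 3 adjusted over the list alone; median 0.31, adjusted p = 0.0833), and WSD1 rose by 0.49 (1 adjusted over the list alone). The light-harvesting (adjusted p = 0.771) and Calvin cycle genes (adjusted p = 0.771), HYH (-0.04), PDF1.2 (-0.15), THI2.1 (0.19), GRX480 (-0.08) and WRKY53 (0.26) did not pass over all probe sets or over their lists alone. GI, at -0.33 (SE 0.13, adjusted p = 0.121), passed only over its list alone.

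In total 2352 probe sets were called for ABA under far-red light, 1151 higher and 1201 lower (48.9% higher), with 152 changed at least 2-fold. Centring each array on its median gave 1321 higher and 896 lower (59.6% higher). It moved the median difference over all probe sets from -0.015 to 0.012. The count was 1518 without far-red replicate 1, 1529 without far-red replicate 2 and 1546 without far-red with ABA replicate 2. Calls were lost for AT5MAT without far-red replicate 1 (0.57) or 3 (0.42), far-red with ABA replicate 1 (0.51) or 2 (0.38), or with only the groups compared. They were lost for XTH19 without far-red replicate 3 (-0.43) or far-red with ABA replicate 3 (-0.46) and for GID1A without far-red replicate 3 (0.32) or far-red with ABA replicate 2 (0.36). EXPA8 lost its call with a trended robust variance (adjusted p = 0.0559, the highest over its alternatives). FMA lost its call without white light with ABA replicate 1 (-0.29), far-red replicate 1 (-0.27) or 2 (-0.26), far-red with ABA replicate 1 (-0.24) or 3 (-0.29). AUR1 lost it without white light with ABA replicate 2 (-0.32), far-red replicate 1 (-0.37), 2 (-0.31) or 3 (-0.28) or far-red with ABA replicate 1 (-0.32), 2 (-0.29) or 3 (-0.35). Both also lost it after median centring or with only the groups compared, and FMA with a trended robust variance. The median of the expansins and endotransglucosylases was -0.072 without far-red replicate 3 (adjusted p = 0.844, range 0.0286 to 0.844 over the alternatives). List tests passed without far-red replicate 2 for the expansins and endotransglucosylases (-0.37) and the gibberellin receptors (0.30), and without far-red with ABA replicate 3 for the latter (0.43) and the cell cycle genes (-0.35). They passed with fry in place of camera for the gibberellin (adjusted p = 0.0168, range 0.0168 to 0.243 over the alternatives), cell cycle (0.0168, range 0.0168 to 0.325) and stomatal genes (0.0080, range 0.0080 to 0.463).

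**Figure D1:**
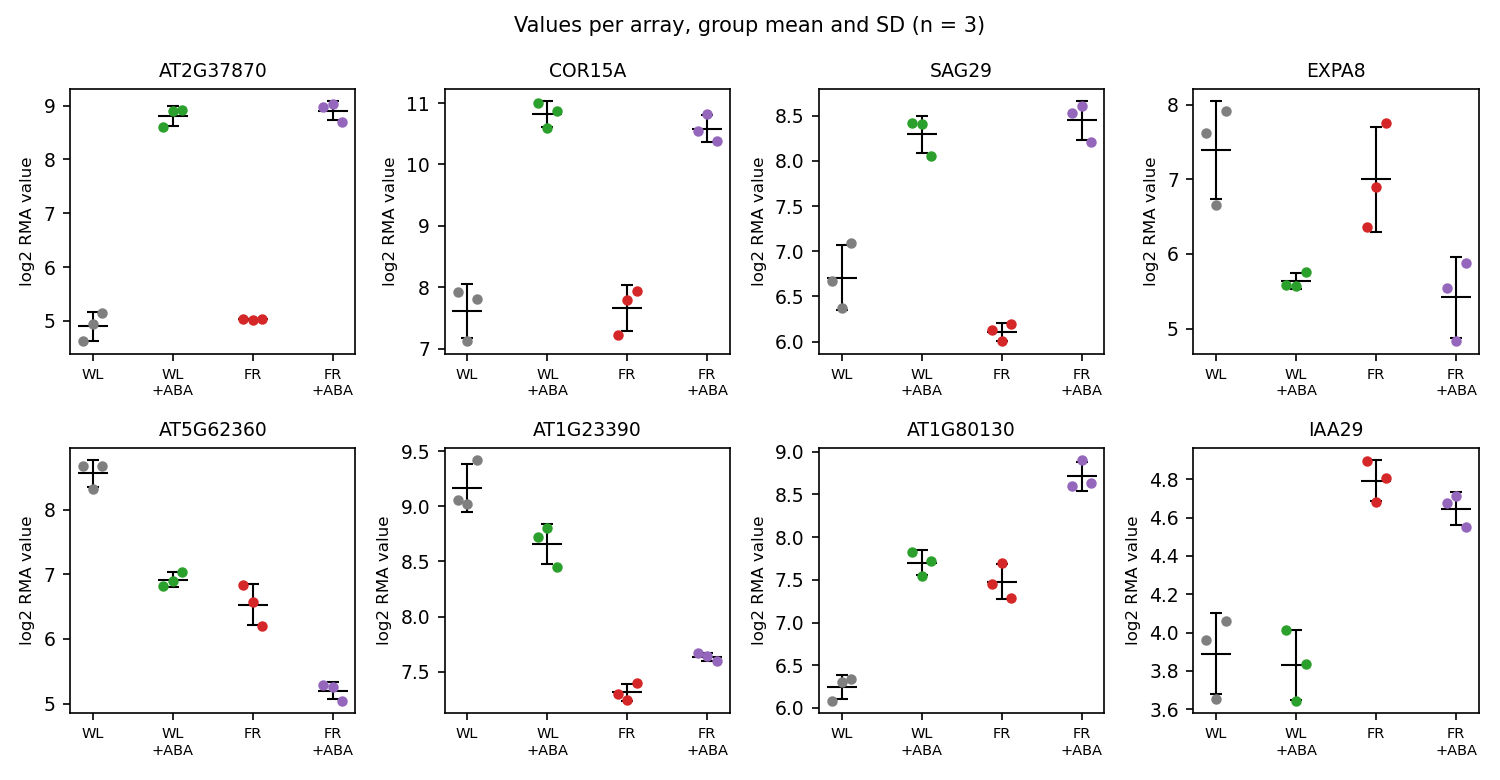
Log2 expression of 8 genes on each of the 12 arrays, by group on the horizontal axis, with points for single arrays and bars for the mean and SD of 3 arrays. AT2G37870, COR15A and SAG29 lie higher and EXPA8 lower on the arrays with ABA in the same light, while at the same ABA level AT5G62360 and AT1G23390 lie lower and AT1G80130 and IAA29 higher on the far-red arrays.

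Far-red light given without ABA changed fewer genes strongly than ABA did, and its strongest changes were falls. AT5G62360, of the family of pectin methylesterase inhibitors, fell 4.09-fold (-2.03, SE 0.14, n = 3 against 3, adjusted p = 2.2e-06). AT1G23390, a Kelch-repeat F-box protein, fell 3.61-fold from 9.17 ± 0.22 to 7.31 ± 0.08 log2 units. AT2G15960 fell 2.74-fold, the thionin gene AT1G66100 2.57-fold, AT2G39400 2.53-fold and the lipid-transfer family member AT1G62510 2.44-fold. Among the rises, AT3G02480 rose 2.81-fold (SE 0.32, adjusted p = 0.0164) and BGLU28 2.70-fold (SE 0.33, adjusted p = 0.0208). AT1G80130 rose 2.36-fold (1.24, SE 0.12, adjusted p = 7.1e-05), the formin gene AT2G43800 2.13-fold and rpl20, a chloroplast ribosomal protein gene of the plastid genome, 1.87-fold. IAA29 (AT4G32280), an auxin-inducible repressor and a widely used shade marker, was called present on none of the white-light arrays and was at least 1.87-fold higher under far-red light (SE 0.12, adjusted p = 6.0e-04). Its level was low there too, at 4.79 log2 units, with a present call on 1 of 3 far-red arrays.

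The early auxin response list moved with far-red light. IAA29, GH3.3 (0.54, SE 0.14) and WES1 (0.51, SE 0.12) rose, 3 of 6 measured genes over all probe sets and 3 adjusted over the list alone, with a median of 0.33 log2 units (camera adjusted p = 0.0185). The call was lost with adjusted p = 0.135 with an estimated correlation, in a range of 8.7e-04 to 0.135 over the alternatives. It was also lost among probe sets called present on all arrays of a group (camera adjusted p = 0.117). This limit leaves out IAA29, which was not called present on all 3 arrays of any group. Of 5 shade markers IAA29 and BIM1 (0.35) rose, 2 adjusted over the list alone, and FHL, YUC2 and HAT2 did not pass (median 0.15, camera adjusted p = 0.0941, and median 0.069 without white light replicate 3). GI, a clock-associated gene, rose by 0.70 (SE 0.13; 1 adjusted over the list alone). XTH19 rose by 0.60 among 8 expansins and endotransglucosylases (1 adjusted over the list alone; median 0.15, adjusted p = 0.249). The median of this list was 0.018 without far-red replicate 3 (adjusted p = 0.989, range 0.0596 to 0.989 over the alternatives), 0.066 without white light replicate 3 and 0.22 without far-red replicate 2. COR15B fell by 0.96 on the log2 scale as the only called ABA-responsive gene, with 2 adjusted over the list alone (median -0.23, adjusted p = 0.0941). SAG29 fell by 0.60 on the log2 scale (1 adjusted over the list alone), and LHCB4.2, an antenna protein of photosystem II, fell by 0.37 on the log2 scale (1 adjusted over the list alone; adjusted p = 0.342).

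No other list had a member called for far-red light without ABA. DFR (0.29), UF3GT (0.28), AT4G14090 (0.45) and AT5MAT (0.35) of the flavonoid pathway did not pass over all probe sets or over the list alone (median 0.32, adjusted p = 0.0941). Nor did GID1A, GID1B and GID1C (median -0.12, adjusted p = 0.336), RCA, PRK and SBPASE (adjusted p = 0.336, with a median whose sign changed from 0.09 to -0.0036 under median centring and which was 0.039 without white light replicate 1), HYH (-0.09), PDF1.2 (-0.83, SE 0.45), THI2.1 (-0.14) or GRX480 (0.01). Adjusted over the list alone, 1 of 3 cell cycle genes (PRL at 0.37, SE 0.11; median 0.18, adjusted p = 0.0941, and median 0.11 without white light replicate 3), 1 of 3 stomatal genes (SPCH at 0.30; median 0.16, adjusted p = 0.192) and WSD1 (0.26) passed. The median of the gibberellin receptors ranged with 1 array left out from -0.18 without far-red replicate 2 to -0.023 without far-red replicate 3.

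Without ABA 1393 probe sets were called between the light conditions, 880 higher and 513 lower under far-red light (63.2% higher), and 45 of them changed at least 2-fold (11 higher and 34 lower). This split depended on the scaling. After quantile normalization it was 574 higher and 578 lower (49.8% higher). After centring it was 361 higher and 1197 lower (23.2% higher). Centring moved the median difference over all probe sets from 0.0026 as deposited to -0.091, and this common shift enters the split. The count fell to 418 without far-red replicate 2, 427 without white light replicate 1, 460 without white light replicate 3 and 625 without far-red replicate 3, and to 642 with only the groups compared in the fit. AT3G02480 lost its call without far-red replicate 3 (1.26) and BGLU28 without white light replicate 1 (1.23), and both with a trended robust variance (adjusted p = 0.0724 and 0.0845). BGLU28, at 0.88 without far-red replicate 1, also lost it with only the groups compared. Calls were further lost for COR15B without white light replicate 1 (-0.83) or 3 (-0.76), far-red replicate 2 (-0.98) or 3 (-0.97) or with a trended robust variance. GH3.3 lost its call without white light replicate 1 (0.56) or 3 (0.46) or far-red replicate 2 (0.38), after quantile normalization (0.45) or centring (0.44), or with only the groups compared. WES1 lost it without white light replicate 1 (0.44), far-red replicate 2 (0.47) or 3 (0.47), and XTH19 without white light replicate 1 (0.60) or 3 (0.58) or far-red replicate 3 (0.51). SAG29 lost its call without white light replicate 1 (-0.62) or 3 (-0.41) or any of far-red replicates 1 (-0.61), 2 (-0.55) and 3 (-0.64). LHCB4.2 lost it without white light replicate 1 (-0.34) or 3 (-0.33) or far-red replicate 2 (-0.30), and both lost it also with only the groups compared. BIM1 lost its call without white light replicate 1 (0.38) or 3 (0.26), far-red replicate 1 (0.35), 2 (0.35) or 3 (0.34), any array of white light with ABA or far-red with ABA replicate 2 (0.35 in each), after quantile normalization (0.28) or centring (0.25), with array weights and with only the groups compared. The ABA-responsive list passed without white light replicate 2 (-0.44), while its median was -0.085 without white light replicate 1. The flavonoid list passed without white light replicate 3 (0.39) or far-red replicate 3 (0.46) and after centring (0.23). With fry in place of camera the shade (adjusted p = 0.0246, range 0.0246 to 0.386 over the alternatives), Calvin cycle (0.0246, range 0.0246 to 0.585), cell cycle (0.0252, range 0.0252 to 0.386) and stomatal lists (0.0246, range 0.0246 to 0.386) passed.

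In the presence of ABA, AT5G62360 again had the largest far-red fall under the naming rule, 3.29-fold (-1.72, SE 0.14, adjusted p = 3.5e-05). AT1G22570 fell 2.36-fold, AT1G66100 2.32-fold, COR15B 2.29-fold (-1.19, SE 0.21, adjusted p = 0.0233), AT1G56300 2.13-fold and AT5G43440 2.11-fold. AT1G80130 rose 2.01-fold (1.01, SE 0.12, adjusted p = 0.0013) and AT5G02580 1.94-fold. IAA29, called present on none of the arrays in white light with ABA and on 2 of 3 in far-red with ABA, was higher, at 4.65 ± 0.08 against 3.83 ± 0.18 log2 units (n = 3, adjusted p = 0.0043). AT5G20790 rose 1.70-fold and AT2G27420 1.57-fold (adjusted p = 0.0485). AT3G02480 and BGLU28, the largest rises named for far-red light without ABA, had lower means under far-red light here. AT3G02480 lay at 8.13 ± 0.47 in far-red with ABA against 8.64 ± 0.34 log2 units in white light with ABA. BGLU28 lay at 4.73 ± 0.14 against 5.03 ± 0.18 (n = 3), and the interaction of neither gene passed limma's test.

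With ABA present, IAA29 was the only member of the shade and early auxin lists past the threshold over all probe sets for far-red light. WES1 had a difference of 0.53 (SE 0.12, adjusted p = 0.0822), as against 0.51 without ABA, and HAT2 one of 0.40 (SE 0.13, adjusted p = 0.238). The 5 shade markers had 2 members past the threshold adjusted over the list alone and a median of 0.20 log2 units (camera adjusted p = 0.0092), which was adjusted p = 0.160 with an estimated correlation, in a range of 0.0010 to 0.544 over the alternatives. The 6 early auxin genes had 2 members adjusted over the list alone and a median of 0.15 (adjusted p = 0.0096; adjusted p = 0.160 with an estimated correlation, range 0.0036 to 0.290). The flavonoid pathway had no member past the threshold over all probe sets, but 3 of 4 adjusted over the list alone. Its values were DFR at -0.35, UF3GT at -0.41, AT4G14090 at -0.24 and AT5MAT at -0.41, with a median of -0.38 (adjusted p = 0.0092; adjusted p = 0.451 with an estimated correlation and 0.311 by fry, range 2.9e-04 to 0.451). COR15B was the only called member of the ABA-responsive list, over all probe sets and over the list alone (median -0.24, adjusted p = 0.0519). XTH19 (0.52, SE 0.13; 1 of 8 adjusted over the list alone; adjusted p = 0.0519), HYH (0.23), GI (0.48) and WSD1 (0.39) passed only over their lists alone. The gibberellin receptors (median -0.05, mean -1.3e-04, upward test, adjusted p = 0.942), the light-harvesting (0.684), Calvin cycle (0.585), cell cycle (0.450) and stomatal genes (0.585), and PDF1.2 (0.24), THI2.1 (-0.05), GRX480 (-0.07), SAG29 (0.15) and WRKY53 (-0.11) did not pass either way.

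With ABA 84 probe sets were called between the light conditions, 18 higher and 66 lower (21.4% higher), and 19 of them changed at least 2-fold. The count was 31 without far-red with ABA replicate 2, 36, 38 and 44 without white light with ABA replicates 2, 1 and 3, and 48 without far-red with ABA replicate 3. It was 149 with a trended robust variance and 137 with array weights. COR15B lost its call without white light with ABA replicate 1 (-1.12) or 3 (-1.09), far-red with ABA replicate 2 (-1.15) or 3 (-1.19), and with a trended robust variance. AT5G20790 lost it without white light with ABA replicate 1 or far-red with ABA replicate 2 (0.66 in both). AT2G27420 lost its call without white light replicate 2, far-red replicates 1, 2 or 3 (0.65 in each), white light with ABA replicate 2 (0.63) or 3 (0.56), or far-red with ABA replicate 1 (0.62), 2 (0.60) or 3 (0.73), after median centring (0.64) and with only the groups compared. Of the lists, the early auxin (0.09) and flavonoid genes (-0.24) lost their calls without far-red with ABA replicate 3. The shade markers lost theirs with the probe sets limited to the upper 60 percent in mean level (camera adjusted p = 0.544). Among probe sets called present on all arrays of a group, the shade markers (camera adjusted p = 0.527) and the early auxin genes (0.290) lost theirs. That limit leaves out IAA29, the only member of either list called here over all probe sets. The ABA-responsive list passed without white light replicate 1 or 2 (-0.24 in both) or white light with ABA replicate 1 (-0.17) or 2 (-0.34), and after quantile normalization (-0.26) or with the present filter (-0.24). The expansins and endotransglucosylases passed without white light with ABA replicate 3 (0.12), far-red replicate 2 or 3 (0.11 in both) or far-red with ABA replicate 2 (0.15), and after quantile normalization or centring (0.09 in both). Their median was 0.038 without far-red with ABA replicate 3, and the ABA-responsive list had adjusted p = 0.651, the highest in a range from 0.0071 over its alternatives, without white light with ABA replicate 3 (-0.21).

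Whether the response to ABA depended on light was tested by the interaction, which is the ABA effect under far-red light minus that in white light. The flavonoid pathway gave the clearest difference. DFR (-0.63, SE 0.20), UF3GT (-0.70, SE 0.24), AT4G14090 (-0.69, SE 0.24) and AT5MAT (-0.77, SE 0.21) had smaller ABA rises under far-red light. The list median was -0.69 (camera adjusted p = 1.3e-05). None of the 4 genes passed limma's test over all probe sets, and 4 of 4 passed adjusted over the list alone. The shift of the list was lost with adjusted p = 0.313 with an estimated correlation and 0.273 by fry, in a range of 1.4e-08 to 0.313 over the alternatives. The mean of the 4 genes was 7.66 ± 0.10 in white light, 9.15 ± 0.17 in white light with ABA, 8.0 ± 0.28 under far-red light and 8.80 ± 0.28 log2 units under far-red light with ABA (SD, n = 3). Its interaction was -0.70, with an exact permutation p of 0.025 over the 400 arrangements of the light labels within ABA levels, two-sided, where 0.005 is the smallest possible.

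**Figure D2:**
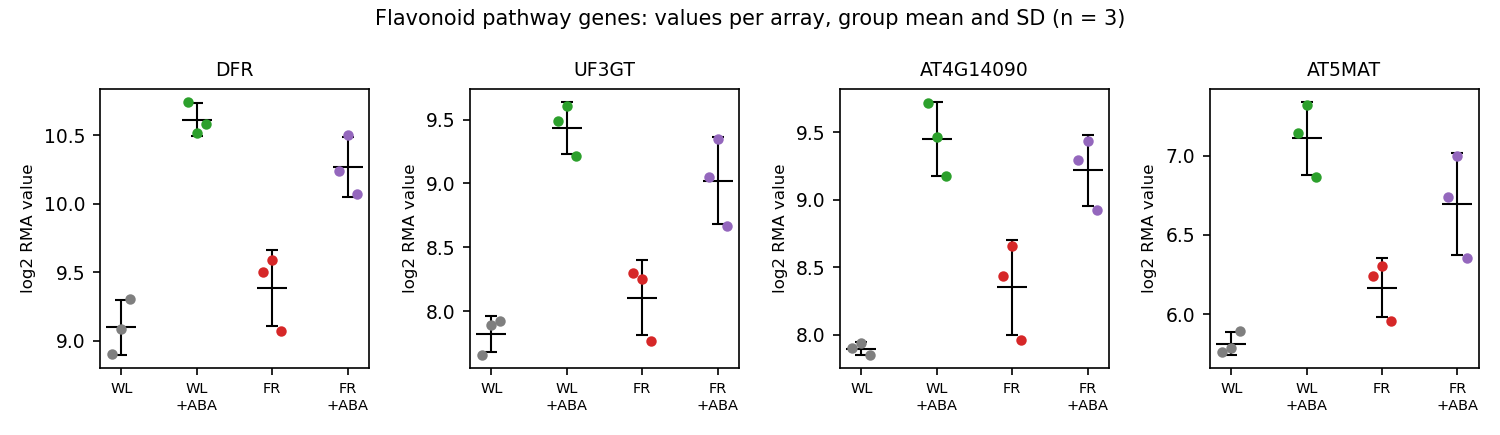
Log2 expression of the flavonoid pathway genes DFR, UF3GT, AT4G14090 and AT5MAT on each of the 12 arrays, by group on the horizontal axis, with points for single arrays and bars for the mean and SD of 3 arrays. Each gene lies higher with ABA in both light conditions, and the step is larger in white light.

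No single probe set passed the interaction test. limma called 0 of 22746 after adjustment, with 1465 at an unadjusted p under 0.05 where chance gives 1137. limma with a trended robust variance called 2, and array weights called 0. Leaving out white light replicate 3 gave 1 call and leaving out far-red replicate 3 gave 2. The smallest adjusted p was 0.40, shared by AT1G23390 (0.83, SE 0.16), AT3G57570 (-0.67, SE 0.12) and NERD (-0.68, SE 0.13), which were chosen after their values were seen. SAG29 had an interaction of 0.75 (SE 0.22, adjusted p = 0.678; 1 adjusted over the list alone), YUC2 of -0.37 (SE 0.14, adjusted p = 0.755; 2 shade markers adjusted over the list alone) and HYH of 0.32 (SE 0.15, adjusted p = 0.763; 1 adjusted over the list alone). The far-red rise of IAA29, called present on none of the white-light arrays without or with ABA, could not be compared between ABA levels. The ABA-responsive (median -0.12, mean 0.01, upward test, adjusted p = 0.889), shade (-0.09, mean 0.03, upward test, adjusted p = 0.794), early auxin (-0.08, adjusted p = 0.709), expansin and endotransglucosylase (adjusted p = 0.794), gibberellin (0.10, adjusted p = 0.655), light-harvesting (adjusted p = 0.709), Calvin cycle (adjusted p = 0.794), cell cycle (-0.16, adjusted p = 0.655), stomatal (-0.12, adjusted p = 0.655) and reference genes (adjusted p = 0.794) did not shift.

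The size of the responses was compared over probe sets called on the averaged effects, which are independent of the interaction. The 1965 probe sets raised by ABA on average had a median ABA effect of 0.35 in white light and 0.38 under far-red light, and the 1949 lowered ones -0.27 and -0.33. The median interactions were 0.03 and -0.06 (permutation p = 0.43 for both). Of the raised and lowered probe sets, 44.2% and 37.0% responded less to ABA under far-red light. The 1205 probe sets raised by far-red light on average had a median far-red effect of 0.39 without ABA and 0.23 with ABA, and 82.8% of them responded less with ABA (median interaction -0.16, permutation p = 0.075, 0.20 after Benjamini-Hochberg adjustment over the 4 sets). The 905 lowered by far-red light had medians of -0.37 and -0.28 (0.11, permutation p = 0.10, 0.20 adjusted). Of these, 70.3% responded less with ABA. The permutation test, which does not use the replicate numbers, passed for neither far-red set, but the outcome depended on the test and the fit, so a smaller far-red response with ABA is left open. The counts of calls differed by 16.6 times, from 5.68 times without white light replicate 3 to 41.1 times without far-red with ABA replicate 2. They were 980 and 137 with array weights and 642 and 76 with only the groups compared. With the rotation test fry in place of the permutation test the raised set passed (p = 0.0426, 0.170 adjusted over the 4 sets), and so it did with array weights (-0.15, fry p = 0.0404). The raised set also passed by fry with the replicate number as a block. The lowered set passed after centring (0.15, permutation p = 0.035), which also turned the median of the set lowered by ABA to 0.02. Centring moved the median interaction over all probe sets from -0.014 to 0.067, and this common shift enters both values. The raised set passed by permutation without white light replicate 2 (-0.22, p = 0.015) or far-red replicate 1 (-0.21, p = 0.030). The lowered set did so without white light replicate 2 (0.16, permutation p = 0.005). For these fits, and for those with a block, array weights or centring, no p adjusted over the 4 sets was computed. Over the alternatives tested by permutation, the p ranged from 0.015 to 0.175 for the raised set and from 0.005 to 0.27 for the lowered set.

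**Figure D3:**
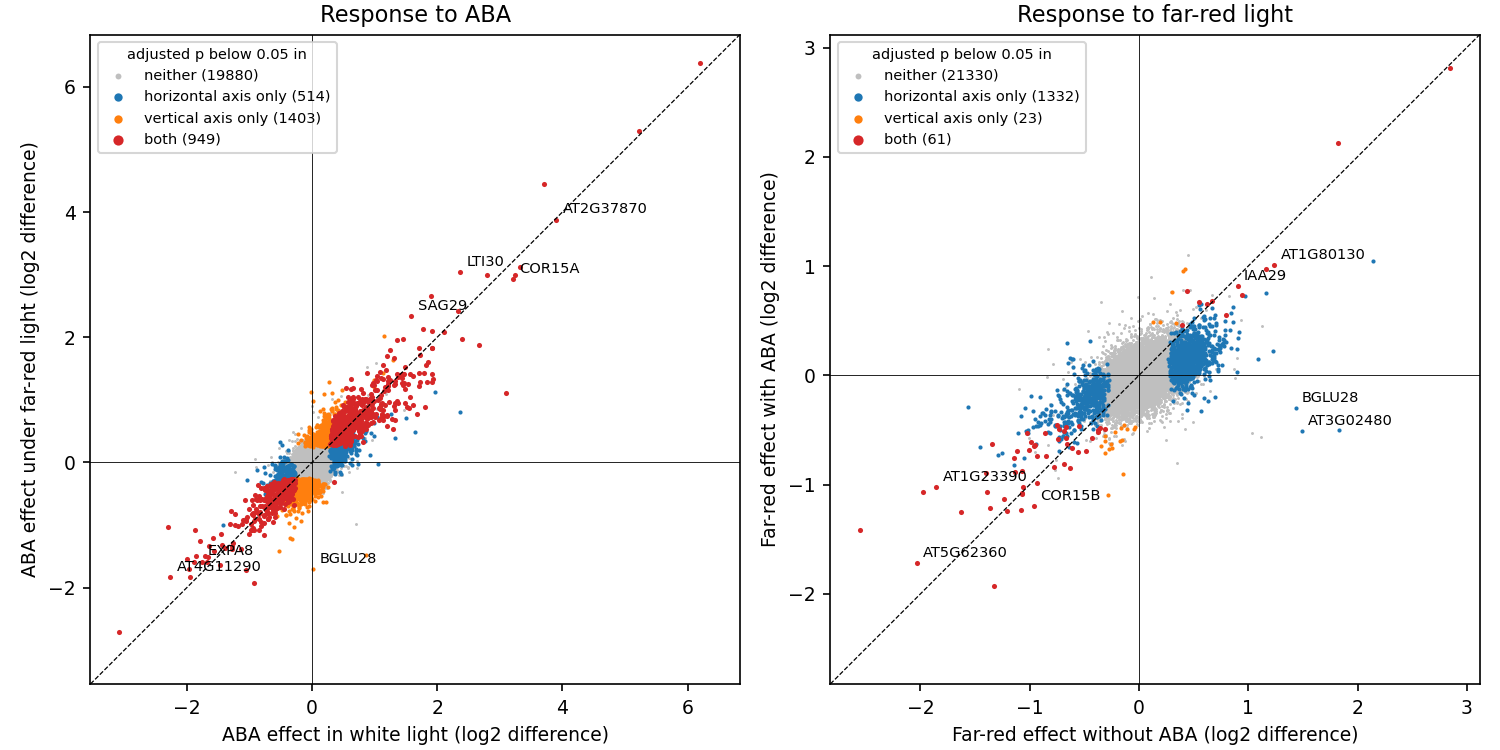
Log2 differences of 22746 probe sets, with the ABA effect in white light against that under far-red light on the left and the far-red effect without ABA against that with ABA on the right. Colours mark probe sets called in both comparisons (949 on the left and 61 on the right), in either alone or in neither.

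The effects of each factor were mostly alike in direction at both levels of the other. Of the probe sets called for ABA in white light, 1424 of 1463 (97.3%) had the same sign under far-red light. Of the called probe sets 609 were called higher and 339 lower in both, against 46.3 and 29.0 for independent lists, and 1 was called in opposite directions. For far-red light, 1272 of 1393 (91.3%) kept their sign with ABA. Of them 12 were called higher and 49 lower at both ABA levels, against 0.696 and 1.49 for independent lists, and 0 in opposite directions by limma. The correlation across probe sets, which are not independent replicates, was r = 0.743 (rho = 0.518) for the ABA effects and r = 0.554 (rho = 0.490) for the far-red effects, and these pairs of comparisons share no arrays. The averaged ABA and far-red effects, with 3914 and 2110 probe sets called, were nearly uncorrelated (r = -0.06, rho = -0.11, covariance -0.0024, jackknife SE of r 0.102). Among probe sets called for both, 268 were lowered by ABA and raised by far-red light (103 for independent lists), 206 raised by ABA and lowered by far-red light (78.2), 132 raised by both (104) and 92 lowered by both (77.5). The averaged far-red split was 57.1% higher as deposited, 49.7% after quantile normalization and 28.8% after centring. Centring took the median of the averaged far-red effect over all probe sets from -3.7e-04 to -0.053. The averaged far-red count was 1133 without white light replicate 3, 1172 and 1227 without white light with ABA replicates 1 and 2, 1223 without far-red replicate 2 and 1291 without far-red with ABA replicate 3.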

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

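All tests of gene families were chosen only after the results were seen, and so was the use of the test with an estimated correlation, itself planned for every list, to weigh an explanation for the flavonoid list.

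The ABA rise of the 4 measured flavonoid and anthocyanin genes DFR, UF3GT, AT4G14090 and AT5MAT was smaller under far-red light than in white light. The median interaction was -0.69 log2 units (camera adjusted p = 1.3e-05, range 1.4e-08 to 0.313 over the alternatives). A single array is argued against, since the median stayed at -0.54 or beyond whichever of the 12 arrays was left out. What stays open is that 4 coregulated genes were counted as nearly independent, as the adjusted p with an estimated correlation was 0.313, and that far-red light may lower the ABA response of the pathway, as a hypothesis found on the same data, for which the mean of the 4 genes gave an exact permutation p of 0.025 over 400 arrangements. These readings cannot be separated with 4 genes of 22 listed, and none of the 4 genes passed limma's interaction test over all probe sets.

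Other differences of the ABA effect between light conditions appeared among families of genes that share the letters of their symbol. The 8 CHR genes had a median interaction of -0.22 (camera adjusted p = 0.0252 over 51 families, 0.796 with an estimated correlation, range 0.0118 to 0.796 over the alternatives), with no member past the threshold over all probe sets. The 7 genes whose symbols begin with PDF had a median interaction of 0.33 (adjusted p = 0.0252, 0.796 with an estimated correlation, range 0.0469 to 0.796), although the letters join plant defensins and peptide deformylases.

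Outside the tested probe sets, 1 of 64 controls, a probe set for a bacterial spike transcript (Bacillus subtilis thr), was 0.35 log2 units higher in far-red with ABA than in far-red (SE 0.09, adjusted p = 0.0203). Its group means were 3.01 in white light, 3.07 in white light with ABA, 2.85 in far-red and 3.20 in far-red with ABA, and it was called present on 0 arrays.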

How the results depend on the processing

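The rotation test of response sizes was chosen after the data were seen, as were all tests of gene families; the other alternatives were planned. No named gene reversed its direction under any alternative. Most alternatives could not have reversed it, since only other scalings, array weights or leaving out an array of the groups compared change the estimated difference. The named genes had also been chosen as called in the main fit. Of their values 2139 kept direction and side of the threshold and 239 only lost the call, 51 of these through the 2-fold minimum and 146 through leaving out an array. The counts of calls were the same in the series value table. Signal over background limits low genes, since 37.5% of probe sets were called absent on the array with the most absent calls.

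The correlations between arrays of the same replicate number were weak. Deviations from group means of same-numbered arrays correlated above 0.1 in 8 of 18 pairs (-0.05 to 0.27). For 1 of 12 arrays the best match had its own number in each of the other groups at once. This is a stricter count than a best match in a single group. On the third principal component, however, replicate 2 scored below 0 in all 4 groups (-10.4, -4.46, -9.13 and -9.43). Replicate 3 scored above 0 in all of them (3.64, 2.33, 15.2 and 12.8). An effect shared by replicates is thus not excluded, and the main fit leaves it out. Of the 6 pairs of groups, far-red and far-red with ABA alone had all 3 correlations above 0.1 (0.12, 0.14 and 0.27). With the replicate number as a block, ABA called 1760 probe sets in white light and 2694 under far-red light. Far-red light called 1762 without ABA and 103 with ABA, and the interaction 0. Without the block these counts were 1463, 2352, 1393, 84 and 0. The median interaction of the set raised by far-red light was -0.16 (p = 0.0084 by fry in place of the permutation test), so that this set passed with the block. As list calls, the block added flavonoid genes for far-red without ABA (0.32) and ABA-responsive genes for far-red with ABA (-0.24).

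The cause of the following changes was not tested. By construction, however, the 2-fold minimum leaves fewer calls, centring moves all interactions alike and the present filter leaves out the shade marker IAA29. Counts became 149 (far-red with ABA) and 2 (interaction) with a trended robust variance, 137 (far-red with ABA) with array weights, 642 (far-red without ABA) with only the groups compared, and 160, 152, 45 and 19 with the 2-fold minimum. After centring, the median interaction of the set lowered by ABA turned to 0.023 (permutation p = 0.66). That of the set lowered by far-red light passed at 0.15 (permutation p = 0.035). The median interaction over all probe sets went from -0.014 to 0.067. Array weights took the set raised by far-red light to -0.15 (p = 0.0404 by fry in place of permutation), and fry without weights gave p = 0.0426 at -0.16, also in place of permutation. The shade markers, at 0.20 with ABA, lost their call with the upper 60 percent (adjusted p = 0.544), the present filter (adjusted p = 0.527) and an estimated correlation (adjusted p = 0.160), and at 0.15 without ABA passed with fry (adjusted p = 0.0246).

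Leaving out each array in turn gave 908 to 1510 calls for ABA in white light, 1518 to 2434 for ABA under far-red light, 418 to 1689 for far-red light without ABA, 31 to 81 with ABA, 0 to 2 for the interaction, 3180 to 3794 for averaged ABA and 1133 to 2571 for averaged far-red light. Median interactions ranged from -0.0054 to 0.055 (raised by ABA), -0.074 to -0.0096 (lowered by ABA), -0.22 to -0.11 (raised by far-red light) and 0.068 to 0.16 (lowered by far-red light), and the correlation of averaged effects from -0.11 to -0.0020. The shade list with ABA stayed between 0.17 and 0.29, while the medians of lists not called moved by over 1.5 times in many of these fits.

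List medians that turned sign were all of lists not called. Quantile normalization gave the light-harvesting list -0.0027 (ABA, white light), -0.064 (ABA, far-red), 0.078 (far-red without ABA), 0.017 (far-red with ABA) and -0.031 (interaction). Centring gave -0.039 for it and -0.030 for reference genes (ABA, white light), -0.0036 for Calvin cycle genes (far-red without ABA), and for the interaction 0.0022 (early auxin), 0.077 (Calvin cycle) and 0.021 (reference). The upper 60 percent and the present filter gave -0.075 for the expansin list (interaction), and the latter 0.10 for early auxin (ABA, white light). Ranges with an array left out that crossed 0 were, for the interaction, -0.21 to 0.085 (ABA-responsive), -0.035 to 0.0042 (Calvin cycle), -0.11 to 0.14 (expansins), -0.014 to 0.11 (light-harvesting) and -0.18 to 0.032 (shade). For ABA in white light they were -0.012 to 0.052 (reference), -0.078 to 0.012 (early auxin), -0.038 to 0.073 (light-harvesting) and -0.082 to 0.015 (stomatal). For ABA under far-red light and far-red light without ABA those of the reference genes were -0.055 to 0.087 and -0.048 to 0.019. For far-red light with ABA they were -0.035 to 0.16 (cell cycle), -0.097 to 0.064 (gibberellin), -0.082 to 0.040 (light-harvesting) and -0.022 to 0.12 (stomatal).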

Other observations

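The families of genes by symbol, the tests of the spread between arrays and of the response size with fry for the far-red calls, and the test of the plastid-encoded genes with an estimated correlation were chosen only after the results were seen; these tests are exploratory.

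The letters ATG stand for autophagy, the recycling of cell contents in vacuoles. Of 8 measured genes whose symbols begin with ATG, 3 fell under far-red light without ABA. All but ATG3 were ATG8 genes, and autophagy genes under other symbols are not among them. ATG8E fell by 0.92 on the log2 scale (SE 0.13, n = 3 against 3, limma adjusted p = 0.0012), ATG8F by 0.55 (SE 0.08, adjusted p = 0.0020) and ATG8H by 0.49 (SE 0.10, adjusted p = 0.0110), all members of the ubiquitin-like family that coats autophagosomes. ATG3 (-0.05), ATG8B (-0.02), ATG8C (-0.40), ATG8D (0.20) and ATG8G (-0.04) did not pass. The median of the 8 genes was -0.22 as deposited, -0.28 after quantile normalization and -0.32 after centring (camera adjusted p = 0.0153 over 51 families, range 0.0017 to 0.607 over the alternatives). The call of the family was lost with an estimated correlation (adjusted p = 0.607) and with fry (adjusted p = 0.0577). With an estimated correlation no family passed in this comparison, and 0.607 was the lowest value of any. With ABA present the far-red difference of ATG8E was -0.43 (SE 0.13, adjusted p = 0.205), and its interaction of 0.50 did not pass (SE 0.18, adjusted p = 0.755), so a dependence on ABA was not shown. Under far-red light ABA raised ATG8H by 0.60 (SE 0.10, adjusted p = 0.0013) and ATG8F by 0.32 (SE 0.08, adjusted p = 0.0225). The fall of ATG8H lost its call without white light replicate 1 (-0.43) or far-red replicate 2 (-0.44). The rise of ATG8F lost it without far-red replicate 2 (0.26) or far-red with ABA replicate 1 or 2 (0.31 in both), or with only the groups compared. In white light the ABA difference of ATG8H was 0.35 (adjusted p = 0.0477) and lost its call without white light replicate 2 (0.32) or 3 (0.31), white light with ABA replicate 1 (0.27), 2 or 3 (0.38 in both), far-red replicates 1, 2 or 3 or far-red with ABA replicate 2 or 3 (0.35 in each). It also lost it after quantile normalization (0.30) or centring (0.29), with a trended robust variance and with only the groups compared.

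Of 69 measured genes of the plastid genome, 6 rose under far-red light without ABA, led by rpl20 (0.91, SE 0.11, adjusted p = 5.1e-04) and rps15 (0.60). The median of the 69 genes was 0.11 log2 units as deposited and after quantile normalization and 0.02 after centring (camera adjusted p = 7.0e-04, range 2.5e-04 to 0.607 over the alternatives). The call of the family was lost with an estimated correlation (adjusted p = 0.607) and with fry (adjusted p = 0.0928). The other 4 calls were lost without some arrays. rpoC1 (0.43) lost it without white light replicate 1 (0.36) or far-red replicate 2 (0.45) or 3 (0.38). accD (0.43) lost it without white light replicate 1 (0.38) or 3 (0.43) or far-red replicate 1 (0.39), 2 (0.47) or 3 (0.41). rbcL (0.32) lost it without white light replicate 1 (0.31), 2 (0.31) or 3 (0.33), white light with ABA replicate 2 (0.32) or far-red replicate 2 (0.27) or 3 (0.28). rps2 (0.29) lost it without white light replicate 1 (0.28), 2 (0.30) or 3 (0.30), white light with ABA replicate 1 or 2 (0.29 in both) or far-red replicate 1 (0.29), 2 (0.27) or 3 (0.33). After centring the calls of accD (0.33), rbcL (0.22) and rps2 (0.20) were lost. With array weights all 3 lost them too, as did rbcL and rps2 with only the groups compared and rbcL after quantile normalization (0.30). The 12 UBP genes, of ubiquitin-specific proteases, had a median of 0.19 in the same comparison (adjusted p = 0.0153, range 0.0145 to 0.607, and 2 of them passed). Their call was lost with an estimated correlation (adjusted p = 0.607) and after quantile normalization (0.13, adjusted p = 0.0699). The 7 plastid rpl genes had a median of 0.23 for far-red light with ABA (adjusted p = 0.0069, range 0.0080 to 0.722), with no member past the threshold. Their call was lost with an estimated correlation (adjusted p = 0.722) and with fry (adjusted p = 0.0822).

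Plastid transcripts mostly lack the long poly(A) tails from which the cRNA was primed, so carry-over of RNA without such tails is a candidate source of their shift. If it were, arrays with more signal on the 25S ribosomal RNA control would have more plastid signal. Over the 12 arrays the deviations from group means correlated with r = 0.063 (permutation p = 0.843; rho = 0.189, p = 0.558; r = 0.121 without the 2 arrays farthest from the median), and subtracting the trend moved the shift from 0.121 to 0.116. With a 95% interval of -0.63 to 0.70 this test decides neither way, and the verdict for so wide an interval was set after the value was seen. Genes of a single genome rising together but counted as independent also remain a possible explanation. The adjusted p with an estimated correlation, 0.607, does not decide it. It was the lowest of any of the 51 families in this comparison and was shared by several, so no family passed. An effect of far-red light on plastid transcripts stays open.

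Far-red light gave 16.6 times fewer calls with ABA than without. The spread between arrays was no larger with ABA, with a ratio of median SDs of 0.907. This ratio cannot bear on the counts, since a variance pooled over the groups gave both far-red comparisons the same median standard error, 0.101 log2 units. With only the groups compared in each fit, the counts were 642 without ABA and 76 with ABA. A shift of the whole distribution is argued against by a ratio of calls of 14 after quantile normalization. A single array is argued against by a ratio of calls that stayed at 5.68 or more whichever array was left out. It was 5.77 and 5.68 without white light replicates 1 and 3, 5.89 and 8.33 without far-red replicates 2 and 3, 31.4, 30.3 and 29.1 without white light with ABA replicates 1, 2 and 3, and 41.1 and 29.7 without far-red with ABA replicates 2 and 3. A smaller far-red response in the presence of ABA may account for it. In the fit without a block, the larger of the 2 adjusted rotation p-values for the sets raised and lowered by far-red light was 0.176. With the replicate number as a block the raised set passed by fry, with no adjustment over the sets computed. The outcome thus depended on the fit, and a smaller response remains a hypothesis. Counts of calls near a threshold exaggerate differences, and the median ratio of the far-red effect with ABA to that without was 0.404 over the 1393 probe sets called without ABA, a selection that favours small ratios.

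Other splits of the arrays were counted for each comparison. For the pairwise comparisons there are only 10 splits of 6 arrays, too few for a share under 0.05. ABA in white light called 1463 probe sets and the highest other split 0, ABA under far-red light 2352 and 0, far-red light without ABA 1393 and 2, and far-red light with ABA 84 and 0. For the averaged effects 1 of 100 splits, the real one, gave as many calls, which argues against chance without excluding it. The calls were 3914 against at most 91 for ABA, and 2110 against at most 220 for far-red light. The other splits mix arrays of the real groups, so the real effect adds to the spread within groups and lowers their counts. For the interaction the real count was 0, so each of the 100 splits gave as many by definition and the count tests nothing. The highest other was also 0 by limma, with 1465 at an unadjusted p under 0.05 in the real data and 2 calls with a trended robust variance.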
